A study of Arabidopsis thaliana and Arabidopsis lyrata subsp. lyrata and Arabidopsis halleri subsp. gemmifera with 10 samples.

How the data were processed

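RNA of mature leaves, taken before flowering, was measured on Affymetrix ATH1 arrays with probes designed on A. thaliana. Per the labels, plants of 3 species and 2 hybrids grew at 22 C with 16 h of light, and biotin-labelled cRNA was made from 500 ng of total RNA, with 2 biological replicates in each of 5 groups. Groups were taken from the sample titles. The deposited values are intensity values, 1 signal per probe set on a linear scale, made by the authors with GCOS and MAS5 per the labels, whose versions are not given in the sources used here. Detection calls were not used here.

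The mean signal trimmed by 2% at each end showed that the deposited arrays were not on a single scale. It was 500 in A. thaliana replicate 1, both A. halleri arrays and both A. thaliana-A. halleri hybrid arrays. It was 136 in A. thaliana replicate 2, 32.8 and 24.3 in A. lyrata, and 55.8 and 50.5 in the A. thaliana-A. lyrata hybrid. The planned use of the values as scaled by the authors therefore did not hold for 5 arrays, and every array was rescaled to a trimmed mean of 500. The 2 sets of 5 arrays are called the scaled and the unscaled class. No depth is known for an array, and the number of arrays limits the precision.

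Of 22810 probe sets, 64 controls were left out. Probe sets were tested if the mean log2 signal of at least 1 group reached the 40th percentile of all values (signal 104), which left 16656, or 73.2%. Tests ran in R 4.3.3 with limma 3.58.1 (lmFit and eBayes with trend = TRUE) on log2(signal + 9.24), the offset being the 10th percentile. All 10 arrays shared a single estimate of the spread per probe set (residual df 5, prior df 4.72). Adjusted p values are Benjamini-Hochberg values within a comparison, and a probe set was called below 0.05. Folds are on the log2(signal + offset) scale.

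The comparisons were the 3 pairs of species, each hybrid against the mean of its parents and against each parent, and the difference between the hybrids' deviations. The mid-parent level was the arithmetic mean of the parents' levels on the linear scale, with an SE by the delta method from limma's variances. Hybrid positions were medians per array over probe sets at least 4-fold apart between the parents. Overlaps were set beside the product of list sizes over probe sets tested, and the correlation and covariance of the differences beside 20 simulations of unchanged groups that shared the A. thaliana arrays.

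Gene names came from a partial table of the array's probe sets: 13513 probe sets had 1 gene, 503 several and 8730 none named here. Of the first, 13436 matched a gene table of assembly TAIR10.1, used for names alone, and 1579 had a symbol other than the locus. No coordinates were used. The series names no genome build. In advance, 23 gene lists were fixed by name, of which 49 of 409 members had a probe set, and chloroplast-encoded and mitochondrial genes were added from the gene table. Most lists are therefore held in small part, and those of flower markers and glucosinolate breakdown had no member measured. The rest cover aliphatic glucosinolate synthesis, anthocyanin and flavonoid synthesis, cell division markers, chlorophyll synthesis, chloroplast-encoded genes, circadian clock, cold and drought response, conserved reference genes, DNA methylation and gene silencing, flowering and vernalization, guard cell markers, heat shock response, indole glucosinolate and camalexin synthesis, iron response, jasmonate and ethylene defence, mitochondrial genes, photosynthesis, nuclear-encoded, salicylic acid and defence, senescence markers, starch metabolism, trichome markers, vascular markers and zinc and other metal homeostasis. Lists with at least 5 measured members were tested with cameraPR at a preset inter-gene correlation of 0.01, and with an estimated correlation.

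Named genes followed a rule fixed at the same time. In the species and mid-parent comparisons it took the 5 genes with the largest higher and lower log2 difference among called probe sets with 1 symbol and with arrays that did not overlap (for mid-parent, both hybrid arrays on the same side of it), at most 2 called members per list by adjusted p, and GI, the only measured gene of those always named. In the other comparisons it took 3 genes per direction. AOP3 in A. lyrata, and the genes of A. thaliana replicate 2, were named outside it, after their values were seen. The procedure was tested on simulated data with 200 changed probe sets among 16656. For A. lyrata against A. thaliana it recovered 4%, 54%, 76% and 92% of changes of log2 1, 2, 3 and 4. For the A. thaliana-A. halleri hybrid against mid-parent it recovered 4%, 54%, 82% and 100%. Changes of 2-fold were thus mostly missed in the simulations. In the data 7161 probe sets were called for A. lyrata against A. thaliana, far more than 200, which loosens the Benjamini-Hochberg cutoff. The simulated shares do not carry over to that comparison. Between 4 and 13 unchanged probe sets were called per comparison.

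Other settings chosen beforehand were no offset or a higher one, no filter or a stricter one, quantile, 75th-percentile and spike-in scaling (18 bacterial and phage control probe sets), eBayes without trend or with robust settings, only the arrays compared, the replicate number as a block, stricter thresholds, only probe sets with plain identifiers, each array left out in turn, a mid-parent on the log scale, and a 2-fold limit for positions. Chosen after seeing the data were the deposited values without rescaling, the scale class as a block, only the arrays of 1 class, spike-in scaling with that block, 1 A. thaliana array for each comparison in the overlaps, and 28 gene families.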

Results

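Transcript levels were measured in mature leaves, collected before flowering, of 3 Arabidopsis species and 2 interspecific hybrids. A. thaliana, represented by the Col accession, is the annual model species whose sequence the array's probes were designed on. A. lyrata ssp. lyrata and A. halleri ssp. gemmifera are perennial relatives, and A. halleri is known for accumulating zinc and cadmium. The hybrids combine A. thaliana with A. lyrata and A. thaliana with A. halleri, and the direction of each cross and the ploidy of the plants are not given in the sources used here. Each of the 5 groups had 2 biological replicates, 1 array each, so that 10 arrays gave all values, and this number limits the precision of every comparison. Signals below are group means ± SD over the 2 arrays after rescaling (arbitrary units), and log2 differences are given ± SE from limma on log2(signal + 9.24), which understates changes of weak probe sets.

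Across the 16656 probe sets tested, which are not independent of each other, replicate arrays correlated with r of 0.878 in A. thaliana, 0.907 in A. lyrata, 0.931 in A. halleri, 0.937 in the A. thaliana-A. lyrata hybrid and 0.953 in the A. thaliana-A. halleri hybrid. A. thaliana leaves correlated less with leaves of the other species, with 0.618 for A. lyrata and 0.656 for A. halleri, while A. lyrata and A. halleri correlated with 0.771. On average each hybrid correlated more with A. thaliana than with its other parent, with 0.810 against 0.769 for the A. lyrata cross and 0.845 against 0.80 for the A. halleri cross, and the hybrids correlated with each other with 0.872. A. thaliana replicate 2 went the other way with replicate 1 of the A. lyrata cross (0.740, against 0.769 and 0.763 with A. lyrata). The first principal component held 42.0% of the variance and ran from A. thaliana through the hybrids to the other species, and the second, with 20.4%, separated the A. halleri arrays from the A. lyrata arrays.

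Leaf signal relative to the hybridization controls on the same arrays differed between the groups. With every array rescaled to the same trimmed mean, the 18 spike-in probe sets were 3.64-fold brighter in A. lyrata than in A. thaliana, 2.49-fold in A. halleri, 1.79-fold in the A. thaliana-A. lyrata hybrid and 1.2-fold in the A. thaliana-A. halleri hybrid. Differences are therefore relative to the average leaf signal of each array, and counts on the spike-in scale are printed beside them. The deposited values also fall into 2 scale classes of 5 arrays: A. halleri, its hybrid and A. thaliana replicate 1 against A. lyrata, its hybrid and A. thaliana replicate 2. Counts with the class as a block and within 1 class are given for the same reason. A. thaliana alone has arrays in both classes, so both fits compare A. lyrata and its hybrid with A. thaliana replicate 2 alone, and A. halleri and its hybrid with replicate 1 alone. Across the classes the block adds the difference between these 2 arrays.

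**Figure D1:**
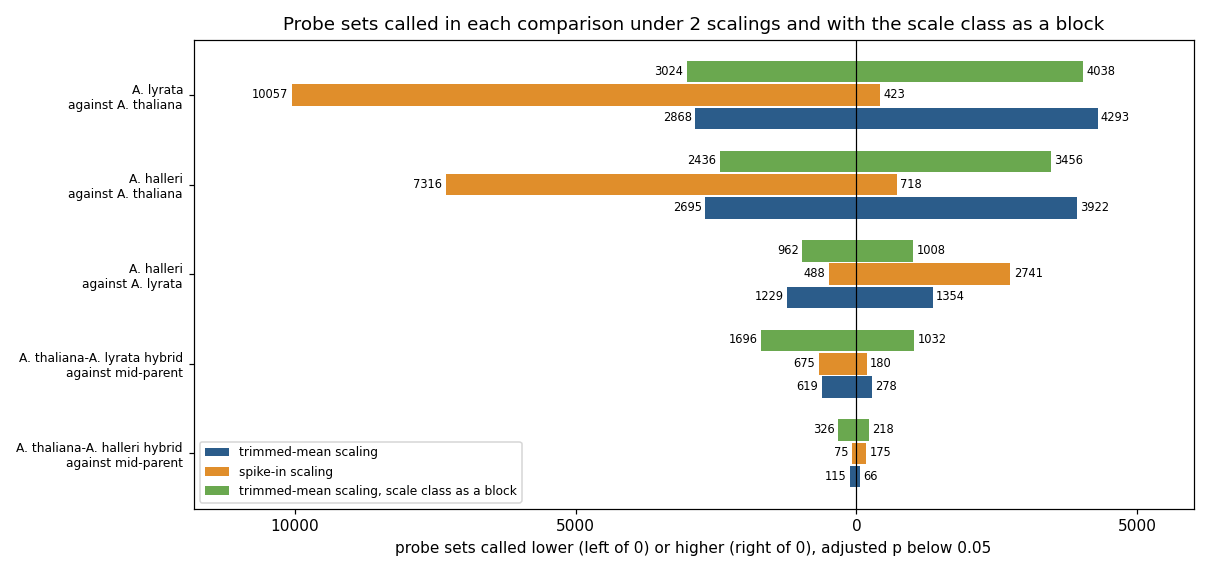
Number of probe sets called higher (right of 0) or lower (left of 0) at an adjusted p below 0.05 in the 3 species comparisons and the 2 mid-parent comparisons, under trimmed-mean scaling, under spike-in scaling, and under trimmed-mean scaling with the scale class as a block. With spike-in scaling the calls of A. lyrata against A. thaliana turn from 4293 higher and 2868 lower to 423 higher and 10057 lower.

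Compared with A. thaliana, leaves of A. lyrata gave stronger signals for many chloroplast-encoded transcripts. Sequence differences from the A. thaliana probes can lower signals in the other species, so a lower signal need not mean fewer transcripts. Among called probe sets with 1 symbol, the largest higher differences were those of CSLA01, CHAT, PDF1.2b, rpoB and ycf3. The largest lower ones were those of CML38, QQS, COR15A, PMEAMT and GLR2.7. CSLA01 (AT4G16590), a cellulose synthase-like gene of mannan synthesis, was at 3.32 ± 0.683 in A. thaliana and 4577 ± 930.0 in A. lyrata, called at adjusted p = 2.22e-05. Its fitted log2 difference was 8.50 ± 0.57. CHAT (AT3G03480), the acetyltransferase that forms the leaf volatile hexenyl acetate, was 149-fold higher (26.7 ± 7.09 against 5292 ± 632, adjusted p = 1.17e-05). The defensin PDF1.2b (AT2G26020) was 93.9-fold higher, on a probe set that can also hybridize with related defensins. The chloroplast genes ycf3, needed for photosystem I assembly, and rpoB, a subunit of the plastid RNA polymerase, were 65.4-fold and 99.6-fold higher. In the other direction, CML38 (AT1G76650), a calmodulin-like calcium sensor, was 107-fold lower and QQS (AT3G30720), an orphan gene known from A. thaliana, 91.4-fold lower. The cold-response gene COR15A (AT2G42540) was at 7245 ± 6889 in A. thaliana and 72.4 ± 61.9 in A. lyrata. PMEAMT, an enzyme of phosphocholine synthesis, was 59.4-fold lower, and GLR2.7, a glutamate receptor-like channel, 58.3-fold lower. By the naming rule, both arrays of the higher group lay above both of the lower group for each of these genes. Without the offset of 9.24 the folds of CSLA01, CML38 and QQS would be over 1.5 times as large.

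Among the lists fixed before the data were examined, 44 of 68 measured chloroplast-encoded genes were higher in A. lyrata and 4 lower (46 and 4 when adjusted over the list alone), with a median log2 difference of 1.61 against 0.31 for all probe sets, and the list stood above other genes (cameraPR adjusted p = 1.11e-10). On the spike-in scale it remained above the rest, with adjusted p = 0.000133, but its median was -0.21 against -1.57 for all. petG, a cytochrome b6f subunit, was at 387 ± 209 in A. thaliana and 9065 ± 219 in A. lyrata. Of 14 mitochondrial genes 6 were higher and 0 lower (6 and 0 over the list alone), among them the cytochrome c maturation gene ccb382 (2.08 ± 0.27) and orfX (2.07 ± 0.32). The list did not pass (adjusted p = 0.117), though it did with an estimated correlation (adjusted p = 0.00983) and with a filter at the 60th percentile (0.0341). Of 5 nuclear photosynthesis genes, RCA, the Rubisco activase, was higher (1.27 ± 0.24, adjusted p = 0.00311), but it was called lower on the spike-in scale (-0.59) and its direction also turned with quantile normalization (-0.28). The list did not pass (adjusted p = 0.525; 2 higher and 1 lower over the list alone). With spike-in scaling 7 chloroplast, 0 mitochondrial and 0 nuclear photosynthesis genes were higher and 20, 4 and 5 lower, and with the class as a block 47, 4 and 3 were higher and 5, 0 and 0 lower.

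Several smaller lists held calls in A. lyrata. In aliphatic glucosinolate synthesis, the methionine aminotransferase BCAT4 was 22.7-fold lower (6414 ± 4266 against 246 ± 75.2), AOP1 was 4.31-fold lower, and the remaining member, AOP3, was higher. UGT74B1, the glucosyltransferase of indole glucosinolate synthesis, was 11-fold lower (adjusted p = 0.000109). The defence gene SAG101 was at 72.2 ± 26.2, against 468 ± 132 in A. thaliana, and the signal of the senescence regulator WRKY53 was lower (-3.46 ± 0.49). Among 4 cold and drought genes, 3 were lower, including COR15B (-2.09 ± 0.42). The heat-shock cochaperone gene AT5G48570 (-1.97 ± 0.45) and the trichome regulator TRY (-1.76 ± 0.33) were lower. Protochlorophyllide reductase PORB was 5.79-fold higher. The tubulin genes TUB5 (2.30 ± 0.50) and TUA6 (-2.07 ± 0.23), 2 of the 4 measured reference genes, went in opposite directions. On the spike-in scale AOP3, PORB, TUB5, ccb382 and orfX were no longer called, and the guard-cell regulator FAMA, listed as FMA (1.27 ± 0.28, -0.51 on the spike-in scale), and the zinc transporter ZIP6 (1.24 ± 0.37, -0.57 on the spike-in scale) changed sign without being called. Members higher and lower were 1 and 2 of 3 for aliphatic glucosinolate synthesis, 1 and 0 of 3 for chlorophyll synthesis, 0 and 3 of 4 for cold and drought response, 2 and 1 of 4 for conserved reference genes, 1 and 0 of 3 for jasmonate and ethylene defence, 0 and 1 of 2 for senescence markers and 1 and 0 of 3 for zinc and other metal homeostasis. Adjusted over the list alone, these counts were 3 and 1 for conserved reference genes, 1 and 1 for jasmonate and ethylene defence and 2 and 0 for zinc and other metal homeostasis, and unchanged for the rest. With spike-in scaling they were 0 and 2 for aliphatic glucosinolate synthesis, 0 and 2 for chlorophyll synthesis, 0 and 4 for cold and drought response, 0 and 3 for conserved reference genes, 0 and 1 for iron response, 1 and 1 for jasmonate and ethylene defence, 0 and 2 for senescence markers, 0 and 3 for starch metabolism and 0 and 1 for zinc and other metal homeostasis. The clock gene GI did not pass (1.29 ± 0.68, adjusted p = 0.146; -0.54 on the spike-in scale). Its A. thaliana arrays were at 162 and 1162, and it was called against replicate 1 alone but not against replicate 2 alone (-0.10, by the block). Of the 27 named calls those of AOP1 and ZIP6 were lost with 1 array left out.

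In limma's fit, 4293 probe sets were higher and 2868 lower in A. lyrata, and 423 were higher and 10057 lower with spike-in scaling, where the median of all probe sets was -1.57. Of the higher calls 423 were kept on the spike-in scale and 274 turned lower, and 2868 of the lower calls were kept. With the scale class as a block 4038 were higher and 3024 lower, and within the unscaled class 3461 and 2655.

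Leaves of A. halleri differed from those of A. thaliana in an overlapping set of genes, with stronger signals again for many chloroplast-encoded transcripts and the defensin PDF1.2b, and for the chlorophyll synthesis gene PORB. CCOAMT (AT1G67980), a caffeoyl-CoA methyltransferase of the phenylpropanoid pathway, was at 127 ± 128 in A. thaliana and 17226 ± 2342 in A. halleri (7.39 ± 0.59, adjusted p = 5.5e-05). PDF1.2b was 165-fold higher, the cytochrome P450 gene CYP71B22 (AT3G26200) 92.2-fold and rpoB 85.4-fold. PORB (AT4G27440), which makes chlorophyllide in the light, was at 627 ± 315 in A. thaliana and 31086 ± 4161 in A. halleri (adjusted p = 1.64e-05). As in A. lyrata, sequence differences from the probes can lower signals here. QQS was 111-fold lower and GLR2.7 32.9-fold lower. The ubiquitin ligase gene RING1 (AT5G10380) was at 10635 ± 3199.9 in A. thaliana and 275 ± 24.2 in A. halleri. The glucosyltransferase genes UGT72B3 (-4.67 ± 0.47) and UGT72E1 (-4.55 ± 0.82) were lower as well. Folds of CYP71B22, QQS, UGT72B3, UGT72E1 and BHLH101 would be over 1.5 times as large without an offset.

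Chloroplast-encoded genes were again mostly higher, with 41 of 68 higher and 4 lower (44 and 5 adjusted over the list alone), a median of 1.55 against 0.32 for all probe sets, and cameraPR adjusted p = 2.56e-10. On the spike-in scale the list still stood above the rest (adjusted p = 2.06e-05). ycf3 was 50.2-fold higher, while ndhD, a subunit of the chloroplast NADH dehydrogenase-like complex, was 9.55-fold lower. Of 14 mitochondrial genes 8 were higher and 0 lower (the same over the list alone), including the cytochrome oxidase gene cox1 (2.55 ± 0.47) and ccb382 (2.2 ± 0.27), and the list passed (adjusted p = 0.0332). It lost that call against A. thaliana replicate 1 alone, by the block (adjusted p = 0.0805), within the scaled class (0.0766) and without replicate 2 (0.0798), and without A. halleri replicate 2 (0.0706). The call was also lost with quantile normalization (0.0706), with only probe sets of plain identifiers (0.0526) and at a threshold of 0.01. Nuclear photosynthesis genes did not pass as a list (adjusted p = 0.663); the Calvin-cycle phosphatase SBPASE was higher (1.45 ± 0.37) and phosphoribulokinase, PRK, lower (-1.04 ± 0.27). With spike-in scaling 17 chloroplast, 2 mitochondrial and 0 nuclear photosynthesis genes were higher and 16, 1 and 3 lower, and with the class as a block 43, 5 and 2 were higher and 5, 0 and 1 lower.

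Members of the smaller lists differed as well. ZIP6 was 4.27-fold higher and bZIP19, a transcription factor of the zinc-deficiency response, 3.31-fold lower (adjusted p = 0.00440), and both were among the 3 measured metal homeostasis genes, all called. In the iron response, the regulator BHLH101 was higher (3.06 ± 0.81) and PYE lower (-1.75 ± 0.60). BCAT4 was 5.93-fold lower, UGT74B1 3.95-fold lower and the glucosinolate dioxygenase gene AOP3 3.32-fold higher. SAG101 (-2.95 ± 0.54) and WRKY53 (-3.14 ± 0.49) were lower. COR15B was 6.91-fold higher and COR47 3.65-fold lower. The sugar exporter SWEET11, a marker of vascular tissue, was at 9117 ± 3897 in A. thaliana and 1066 ± 317 in A. halleri. TUB5 (3.71 ± 0.50) and TUA6 (-2.13 ± 0.23) again went in opposite directions, FMA was 2.68-fold higher, AT5G48570 was lower (-1.63 ± 0.45), and the chlorophyll precursor enzyme GSA1 (1.37 ± 0.41) and the clock gene GI (1.90 ± 0.68, adjusted p = 0.0486) were higher. Members higher and lower were 1 and 1 of 3 for aliphatic glucosinolate synthesis, 2 and 0 of 3 for chlorophyll synthesis, 1 and 2 of 4 for cold and drought response, 1 and 1 of 4 for conserved reference genes, 1 and 1 of 2 for iron response, 1 and 0 of 3 for jasmonate and ethylene defence, 0 and 1 of 2 for senescence markers, 1 and 0 of 4 for starch metabolism and 2 and 1 of 3 for zinc and other metal homeostasis. Adjusted over the list alone, these counts were 1 and 2 for aliphatic glucosinolate synthesis and 1 and 3 for cold and drought response, and unchanged for the rest. With spike-in scaling they were 0 and 2 for aliphatic glucosinolate synthesis, 1 and 1 for chlorophyll synthesis, 1 and 3 for cold and drought response, 1 and 3 for conserved reference genes, 0 and 1 for iron response, 1 and 1 for jasmonate and ethylene defence, 0 and 0 for starch metabolism and 0 and 1 for zinc and other metal homeostasis. The class as a block gave 0 and 1 for aliphatic glucosinolate synthesis, 1 and 1 for chlorophyll synthesis, 0 and 1 for iron response and 1 and 1 for zinc and other metal homeostasis. PWD, which phosphorylates starch, was higher (1.19 ± 0.38, -0.11 on the spike-in scale). Another probe set, matched by the same symbol and not by locus, was not called (-0.52) and may belong to another gene. On the spike-in scale AOP3, GSA1, GI, FMA, BHLH101, SBPASE, PWD and ZIP6 were not called, and with the scale class as a block AOP3, GSA1, AT5G48570, BHLH101 and PWD were not. The GI call was kept against A. thaliana replicate 1 alone (3.29, adjusted p = 9.32e-05 by the block) and lost when any array other than replicate 2 was left out. Of the 35 named calls 25 held with each array left out in turn, without AOP3, GSA1, GI, COR47, AT5G48570, BHLH101, PYE, SBPASE, PRK and PWD.

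In all, 3922 probe sets were higher and 2695 lower in A. halleri, 718 and 7316 with spike-in scaling (median of all probe sets 0.32 and -1.02), 3456 and 2436 with the class as a block, and 4047 and 2644 within the scaled class. The total of 6617 dropped to 4208 without A. halleri replicate 1 and to 3670 without replicate 2.

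Many probe sets differed from A. thaliana in both species. A total of 2534 were higher in both and 1710 lower in both, and 111 were called in opposite directions. Independent lists of these sizes would share 1011 higher and 464 lower calls. Across probe sets the 2 differences correlated with r = 0.735, against 0.503 in 20 simulations of unchanged species that shared the A. thaliana arrays, and their covariance was 1.95 against 0.135. Part of the excess may come from the shared arrays. With 1 A. thaliana array for each comparison, a split chosen after seeing the data, none is shared and the covariance was 1.65 and 1.68 in the 2 assignments (r = 0.556 and 0.578), with 3160 and 3125 calls shared in direction. Without A. halleri replicate 2 the 4244 shared calls dropped to 2576, and with spike-in scaling 232 were higher and 6663 lower in both.

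A. halleri and A. lyrata differed from each other in fewer probe sets than either did from A. thaliana, and no list tested passed. CML37 (AT5G42380), a calmodulin-like protein, was at 55.5 ± 34.1 in A. lyrata and 3403 ± 709.6 in A. halleri (5.81 ± 0.55, adjusted p = 0.000310). The vacuolar protease gene GAMMA-VPE was 43.1-fold higher in A. halleri, the methionine sulfoxide reductase gene MSRB9 33.4-fold, the chitinase gene ChiC 32.6-fold, and COR15B 29.5-fold. CHAT was 46.7-fold lower in A. halleri than in A. lyrata, the spindle checkpoint gene BUB3.2 34.8-fold, PGM 16.3-fold, the ubiquitin-conjugating enzyme UBC30 12.4-fold, and BSMT1, which makes methyl salicylate and methyl benzoate, 12.3-fold. Folds of BUB3.2, PGM and BHLH101 would be over 1.5 times as large without an offset.

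Within the fixed lists, PORB (3.16 ± 0.37) and GSA1 (1.44 ± 0.41), 2 of 3 chlorophyll synthesis genes, were higher in A. halleri. So were COR15A (3.95 ± 0.75), BHLH101 (3.48 ± 0.81), BCAT4 (1.94 ± 0.50), UGT74B1 (1.48 ± 0.33), TRY (1.5 ± 0.33), SBPASE (1.3 ± 0.37) and PWD (2.15 ± 0.38). The probe set matched to PWD by symbol alone was at -0.56. SWEET11 was 10.1-fold lower, bZIP19 3.59-fold, RCA 2.25-fold and TUB6 2.01-fold. Of 68 chloroplast genes 2 were higher, such as the ATP synthase subunit gene atpI (1.54 ± 0.29), and 3 lower, such as the photosystem II gene psbI (-1.01 ± 0.24); over the list alone 2 were higher and 2 lower. The chloroplast, mitochondrial and nuclear photosynthesis lists did not pass (adjusted p = 0.759 for each). With spike-in scaling 5 chloroplast, 1 mitochondrial and 2 nuclear photosynthesis genes were higher and 0, 0 and 0 lower, and with the class as a block 12, 0 and 0 were higher and 7, 0 and 1 lower. Members higher and lower were 1 and 0 of 3 for aliphatic glucosinolate synthesis, 2 and 0 of 3 for chlorophyll synthesis, 2 and 0 of 4 for cold and drought response, 0 and 1 of 4 for conserved reference genes, 1 and 0 of 2 for iron response, 1 and 0 of 4 for starch metabolism and 0 and 1 of 3 for zinc and other metal homeostasis. Adjusted over the list alone, these counts were 1 and 1 for conserved reference genes, and unchanged for the rest. With spike-in scaling they were 1 and 0 for conserved reference genes and 1 and 1 for zinc and other metal homeostasis. The class as a block gave 0 and 0 for aliphatic glucosinolate synthesis, 1 and 1 for chlorophyll synthesis, 1 and 0 for cold and drought response, 0 and 1 for iron response and 0 and 0 for starch metabolism. GI did not pass (0.61 ± 0.68), and its call with the block (3.39, adjusted p = 0.00161) comes from the added difference between the A. thaliana arrays. In all 1354 probe sets were higher and 1229 lower in A. halleri, 2741 and 488 with spike-in scaling (median 0.52), which ended the calls of psbI, TUB6 and RCA. The 2 species lie in different scale classes, so no value within 1 class exists; the block fit, which adds the difference between the A. thaliana arrays, gave 1008 and 962 and kept 14 of the 25 named calls, without ChiC, BSMT1, BCAT4, GSA1, COR15A, TUB6, UGT74B1, BHLH101, SBPASE, PWD and TRY. With each array left out in turn 10 of the 25 named calls held, those of CML37, GAMMA-VPE, MSRB9, COR15B, CHAT, BUB3.2, PGM, UBC30, PORB and SWEET11. The total of 2583 dropped to 1569 and 1256 without A. lyrata replicates 1 and 2, and to 1115 and 1110 without A. halleri replicates 1 and 2.

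The A. thaliana-A. lyrata hybrid was compared with the mean of its parents' signals. Additive expression would give this for nuclear genes at equal dosage of both genomes, which was not tested. Organelle genes inherited from 1 parent would not follow it, so for them it is only a reference. Of the named genes, CML38, STZ, CHI, rpoB and ycf3 lay furthest below this mean and BHLH101, SKU5, UGT84B1, ARR15 and MSRB6 furthest above it. CML38 was at 18.6 ± 17.7 in the hybrid, compared with 3798 ± 2778 in A. thaliana and 26.8 ± 27.3 in A. lyrata, 66.1-fold below mid-parent (-6.05 ± 0.73, adjusted p = 0.00465). STZ (AT1G27730), a zinc-finger repressor induced by stress, was at 182 ± 109 in the hybrid, 9913 ± 4034 in A. thaliana and 4050.0 ± 4635 in A. lyrata. A chitinase gene, CHI (AT2G43570), was 29.4-fold below mid-parent. The chloroplast genes rpoB (-4.92 ± 0.70) and ycf3 (-4.84 ± 0.30) stayed near the A. thaliana level, with ycf3 at 231 ± 71.7 in the hybrid, 198 ± 59.3 in A. thaliana and 13282 ± 287 in A. lyrata. BHLH101 (AT5G04150) was at 416 ± 116 in the hybrid against 28.1 ± 34.2 and 13.2 ± 9.85 in the parents (4.07 ± 0.70, adjusted p = 0.0151). SKU5, a cell-wall protein of directional growth, was 7.78-fold above mid-parent, the auxin glucosyltransferase UGT84B1 6.34-fold, the cytokinin response regulator ARR15 4.99-fold, and MSRB6 4.89-fold. Without an offset the folds of BHLH101, UGT84B1 and CML38 would be over 1.5 times as large, and UGT84B1 would not be called. For CML38 the hybrid arrays stood at 6.12 and 31.1.

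Of 68 chloroplast-encoded genes 15 were below mid-parent and 2 above (19 and 3 adjusted over the list alone), with a median of -0.40 against -0.18 for all probe sets and cameraPR adjusted p = 9.48e-06; petG was at 397 ± 46.6 in the hybrid. The list did not pass with spike-in scaling (adjusted p = 0.143). Of 14 mitochondrial genes 3 were below and 0 above (10 and 0 over the list alone), including nad4, a subunit of respiratory complex I (-2.08 ± 0.31), and ccb382 (-2.02 ± 0.25), with adjusted p = 2.02e-06. The 5 nuclear photosynthesis genes stood above other genes (median 1.1, adjusted p = 2.11e-06; 0.0105 with an estimated correlation), with 1 called alone, PRK (1.55 ± 0.24), and 4 over the list alone. With spike-in scaling 0 chloroplast, 0 mitochondrial and 2 nuclear photosynthesis genes were above and 8, 3 and 0 below, and with the class as a block 4, 0 and 4 were above and 25, 6 and 0 below. BCAT4 was at 14196 ± 6190.2, 4.57-fold above mid-parent, and UGT74B1 2.56-fold above. WRKY53 (-2.54 ± 0.47), COR47 (-2.22 ± 0.39) and PORB (-1.52 ± 0.35) lay below, and TUA6 (1.37 ± 0.21) above. Members higher and lower were 1 and 0 of 3 for aliphatic glucosinolate synthesis, 0 and 1 of 3 for chlorophyll synthesis, 0 and 1 of 4 for cold and drought response, 1 and 0 of 4 for conserved reference genes, 1 and 0 of 2 for iron response and 0 and 1 of 2 for senescence markers. Adjusted over the list alone, these counts were 2 and 0 for aliphatic glucosinolate synthesis, 2 and 1 for chlorophyll synthesis, 0 and 2 for cold and drought response, 2 and 1 for conserved reference genes and 0 and 2 for senescence markers, and unchanged for the rest. With spike-in scaling they were 0 and 0 for aliphatic glucosinolate synthesis, 0 and 0 for chlorophyll synthesis, 0 and 2 for cold and drought response and 0 and 0 for conserved reference genes. The class as a block gave 2 and 1 for chlorophyll synthesis, 2 and 0 for conserved reference genes and 0 and 1 for starch metabolism. GI did not pass (-0.60 ± 0.60), though it was called against A. thaliana replicate 2 alone (-1.16, adjusted p = 0.00798 by the block).

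Above mid-parent were 278 probe sets and below it 619; with spike-in scaling 180 were above and 675 below, with the class as a block 1032 and 1696, and within the unscaled class 782 and 1139. With a mid-parent on the log scale, which cannot exceed the arithmetic mean, the split turned to 544 above and 398 below. Of the 20 named calls spike-in scaling ended those of UGT84B1, MSRB6, BCAT4, PORB, TUA6 and UGT74B1, and the class as a block that of UGT84B1. The 897 calls became 36 and 347 without hybrid replicates 1 and 2, 439 and 415 without A. lyrata replicates 1 and 2, 2764 without A. thaliana replicate 1, 514 and 510 without A. halleri replicates 1 and 2, and 500 and 490 without A. thaliana-A. halleri hybrid replicates 1 and 2. CHI, ycf3, petG and ccb382 kept their calls with each of the 10 arrays left out in turn, and the other 16 named calls did not.

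In the A. thaliana-A. halleri hybrid, AOP3 (AT4G03050) departed most from mid-parent among called probe sets with 1 symbol. Its enzyme forms hydroxyalkyl glucosinolates. AOP3 was at 8978 ± 1041 in the hybrid against 19.9 ± 11.2 in A. thaliana and 90.6 ± 50.9 in A. halleri, 148-fold above mid-parent (7.21 ± 0.55, adjusted p = 0.000760), and its call held with each array left out in turn. The other 13 named calls of this comparison were each lost with at least 1 array left out. ATPMEPCRB, a pectin methylesterase gene, was 5.89-fold above, XTH32, which remodels xyloglucan in cell walls, 5.04-fold, and the chloroplast genes rps4, a ribosomal protein, and ndhD 5.0-fold and 4.25-fold. QQS was 36.0-fold below mid-parent, SUFE2, a factor of iron-sulfur cluster assembly, 26.6-fold, and the pyruvate decarboxylase gene PDC2 8.51-fold. rpoB (-3.74 ± 0.70) and ycf3 (-3.05 ± 0.29) lay below, with ycf3 at 621 ± 25.1 in the hybrid and 10222 ± 838 in A. halleri. QQS stood at 7.71 and 43.3 on the hybrid arrays, and the folds of QQS and SUFE2 would be over 1.5 times as large without an offset.

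Of 68 chloroplast-encoded genes 3 were above mid-parent and 3 below (14 and 6 over the list alone), and the list stood slightly above other genes (median 0.14 against -0.12, adjusted p = 0.00588). That call was lost without hybrid replicate 1 (adjusted p = 0.153) and within the scaled class (0.0640). Of 14 mitochondrial genes 1, nad4 (-1.92 ± 0.31), was below and 0 above (2 and 0 over the list alone), with adjusted p = 0.00588 for the list, 0.0615 with spike-in scaling and 0.0786 with a filter at the 60th percentile. Nuclear photosynthesis genes again stood above other genes (median 0.60, adjusted p = 0.000108; 0.0283 with an estimated correlation), with PRK called (1.39 ± 0.24) and 3 called over the list alone. With spike-in scaling 8 chloroplast, 0 mitochondrial and 2 nuclear photosynthesis genes were above and 1, 0 and 0 below, and with the class as a block 11, 0 and 1 were above and 5, 1 and 0 below. PORB (-2.03 ± 0.37) and COR15B (-2.56 ± 0.39) were below mid-parent, and GI did not pass (-1.2 ± 0.62), though it was called against A. thaliana replicate 1 alone (-1.0, adjusted p = 0.0436 by the block, but not within the scaled class) and against replicate 2 alone. Members higher and lower were 1 and 0 of 3 for aliphatic glucosinolate synthesis, 0 and 1 of 3 for chlorophyll synthesis, 0 and 1 of 4 for cold and drought response, 0 and 0 of 4 for conserved reference genes, 0 and 0 of 2 for iron response and 0 and 0 of 3 for jasmonate and ethylene defence. Adjusted over the list alone, these counts were 2 and 0 for aliphatic glucosinolate synthesis, 1 and 1 for chlorophyll synthesis, 0 and 2 for cold and drought response, 2 and 1 for conserved reference genes, 0 and 1 for iron response and 1 and 1 for jasmonate and ethylene defence, and unchanged for the rest. With spike-in scaling they were 0 and 0 for chlorophyll synthesis. The class as a block gave 0 and 2 for cold and drought response and 0 and 2 for iron response. In all 66 probe sets were above and 115 below; with spike-in scaling the split turned to 175 above and 75 below, with the median of all probe sets at 0.21 in place of -0.12, and the calls of rpoB, PORB and nad4 ended. With the class as a block 218 were above and 326 below, and within the scaled class 122 and 192. With the log-scale mid-parent the split turned as well, to 266 above and 93 below. The 181 calls became 12 and 6 without hybrid replicates 1 and 2, 24 and 12 without A. halleri replicates 1 and 2, 1254 and 598 without A. thaliana replicates 1 and 2, 62 and 62 without A. lyrata replicates 1 and 2, and 24 and 24 without A. thaliana-A. lyrata hybrid replicates 1 and 2.

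**Figure D2:**
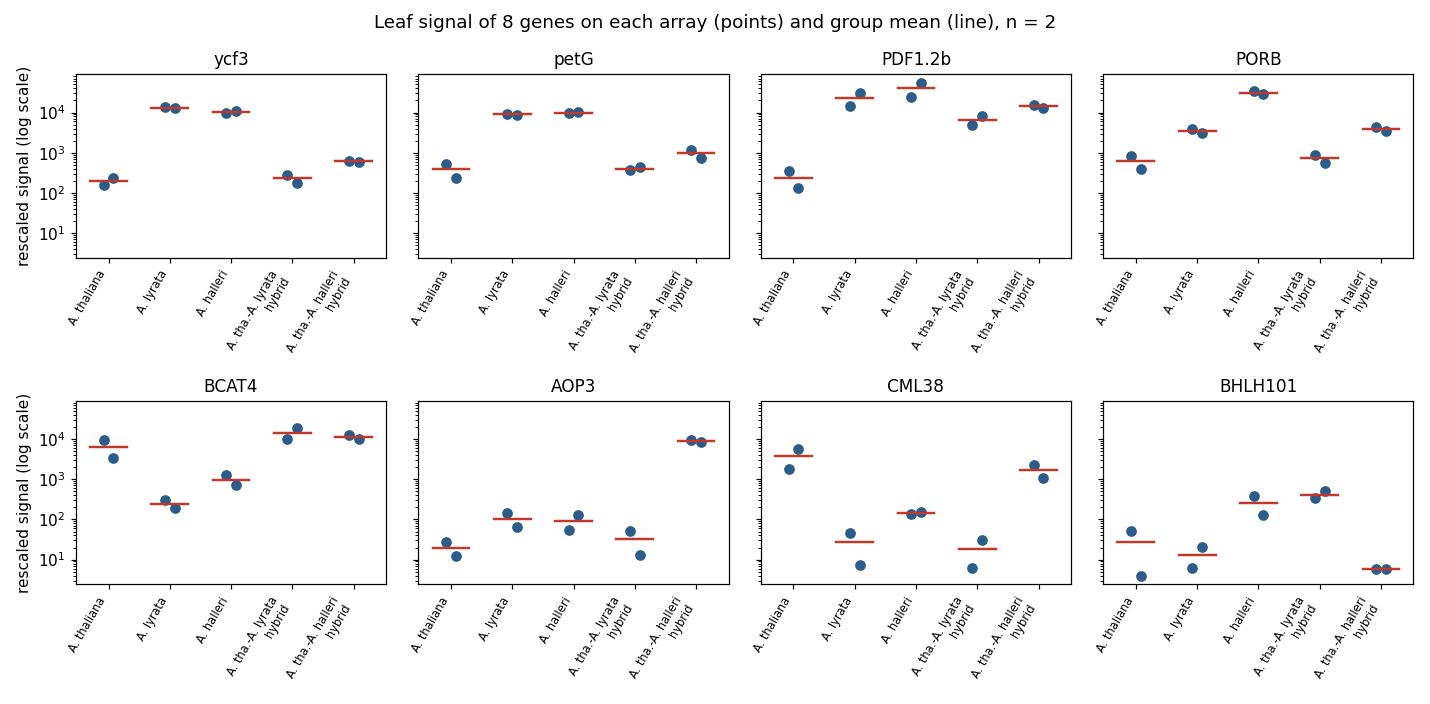
Rescaled leaf signal (log axis, arbitrary units) of 8 named genes on each of the 10 arrays (points), with the mean of the 2 arrays of each group (line). ycf3 and petG are bright in A. lyrata and A. halleri and near the A. thaliana level in the A. thaliana-A. lyrata hybrid, and AOP3 is bright in the A. thaliana-A. halleri hybrid, at 8978 ± 1041 (SD), and at 105 or less on average in the other groups.

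The hybrids were also compared directly, as a test of the difference between their deviations from mid-parent. BHLH101 deviated upward in the A. lyrata cross relative to the A. halleri cross by 7.20 ± 1.02 (log2, adjusted p = 0.0118), the copper chaperone gene CCS by 2.71 ± 0.51, and ECS1 by 2.26 ± 0.30. AOP3 (-8.07 ± 0.78), CML38 (-5.92 ± 0.73) and STZ (-4.84 ± 0.90) deviated upward in the A. halleri cross relative to the A. lyrata cross. AOP3 alone kept its call with each array left out in turn, and BHLH101, CCS, ECS1, CML38 and STZ each lost it with some array left out. Without an offset the values of BHLH101 and CML38 would be over 1.5 times as large on the linear scale. In all 50 probe sets differed in the first direction and 123 in the second, 40 and 353 with spike-in scaling, which ended the call of CCS, and 295 and 389 with the scale class as a block. Each hybrid lies in a scale class of its own, so no value within 1 class exists. The total of 173 became 25 and 70 without A. thaliana-A. lyrata hybrid replicates 1 and 2, 34 and 16 without A. thaliana-A. halleri hybrid replicates 1 and 2, 99 and 77 without A. halleri replicates 1 and 2, and 457 and 402 without A. thaliana replicates 1 and 2.

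Departures from mid-parent overlapped between the hybrids. A total of 24 probe sets were above mid-parent in both and 39 below in both, with 5 in opposite directions, against 1.1 and 4.27 for independent lists. With the log-scale mid-parent 125 were above in both and 27 below in both. rpoB, ycf3, PORB and nad4 lay below mid-parent in both hybrids and PRK above in both. The deviations correlated across probe sets with r = 0.389, against 0.158 in 20 simulations of unchanged hybrids on the same A. thaliana arrays, and their covariance was 0.244 against 0.0343. Part of this may come from the shared A. thaliana arrays. With 1 A. thaliana array for each comparison, a split chosen after seeing the data, none is shared and the covariance was 0.214 and 0.132 in the 2 assignments (r = 0.318 and 0.182), and the 259 and 165 shared calls rest on a spread without the difference between the A. thaliana arrays. The 63 shared calls became 1 and 4 without A. thaliana-A. lyrata hybrid replicates 1 and 2, 5 and 1 without A. thaliana-A. halleri hybrid replicates 1 and 2, 17 and 17 without A. lyrata replicates 1 and 2, 6 and 3 without A. halleri replicates 1 and 2, and 710 and 171 without A. thaliana replicates 1 and 2.

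Measured anthocyanin, flowering, cell-division and DNA-demethylation genes gave no calls in the 3 species and 2 mid-parent comparisons, though some settings called them. limma called 0 of the 3 anthocyanin genes DFR, UF3GT and AT5MAT, with 1 value at an unadjusted p below 0.05, though with the scale class as a block it called 0 higher and 3 lower in A. lyrata against A. thaliana, 1 higher and 0 lower in A. halleri against A. thaliana, 2 higher and 0 lower in A. halleri against A. lyrata and 0 higher and 2 lower in the A. thaliana-A. lyrata hybrid against mid-parent. These block calls rest on 1 A. thaliana array each, or on the difference between the A. thaliana arrays (DFR at 12.9 and 13384) in A. halleri against A. lyrata. With spike-in scaling it called 1 of them lower in A. halleri against A. thaliana. limma also made no call for the replication gene PRL (0 unadjusted), the flowering gene AGL24 (0 unadjusted) and the DNA demethylase gene DME (1 unadjusted), each the single measured member of its list. With the scale class as a block PRL and AGL24 were called higher in A. lyrata than in A. thaliana replicate 2 alone (log2 1.65 and 1.45), and with spike-in scaling DME was called lower in A. lyrata than in A. thaliana and than in A. halleri. Of the 15 cameraPR results of the chloroplast, mitochondrial and nuclear photosynthesis lists, all 9 that passed also passed with an estimated correlation.

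Set against each parent, both hybrids had more probe sets called against their other parent alone than against A. thaliana alone. In the A. thaliana-A. lyrata hybrid CSLA01 was 116-fold, PDF1.2b 28.1-fold and the expansin gene EXPB1 15.9-fold above A. thaliana, and CML38 131-fold, CHI 56.9-fold and STZ 54.2-fold below it. The same hybrid exceeded A. lyrata 88.9-fold for PMEAMT, 84.7-fold for ECS1 and 54.1-fold for BCAT4, and lay 60.1-fold, 56.6-fold and 22.4-fold below it for rpoB, ycf3 and petG. In the A. thaliana-A. halleri hybrid AOP3 (319-fold), PDF1.2b (63.6-fold) and CSLA01 (51.4-fold) exceeded A. thaliana, and QQS (71.4-fold), SUFE2 (49.4-fold) and the immune receptor gene CSA1 (14.8-fold) lay below it. Against A. halleri, AOP3 (96.1-fold), the thylakoid gene TROL (34.0-fold) and RING1 (26.9-fold) were higher and rpoB (26.5-fold), ycf3 (16.2-fold) and BHLH101 (15.7-fold) lower. All of these 24 calls held with spike-in scaling, and all but that of EXPB1 with the scale class as a block, and 20 held with each array left out in turn, without those of EXPB1, STZ, CSA1 and BHLH101. Folds of CSLA01, EXPB1, CML38, AOP3, QQS, SUFE2 and BHLH101 would be over 1.5 times as large without an offset.

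The A. thaliana-A. lyrata hybrid had 1100 probe sets above and 825 below A. thaliana, and 1720 above and 1705 below A. lyrata. The A. thaliana-A. halleri hybrid had 666 above and 333 below A. thaliana, and 1459 above and 1049 below A. halleri. With spike-in scaling these became, in the same order, 352 and 4067, 5223 and 168, 442 and 535, and 5534 and 110. With the class as a block they were 1998 and 1568, 2293 and 2589, 773 and 422, and 2047 and 1870, and within 1 class 1606 and 1162, 1931 and 1881, 751 and 414, and 2216 and 2220. Above both parents were 124 probe sets in the A. lyrata cross and 57 in the A. halleri cross, and below both 120 and 36. Of the probe sets that differed between the parents, 1193 in the A. lyrata cross were called against A. thaliana alone, 2393 against A. lyrata alone, 261 between both and 3271 against neither, and in the A. halleri cross these were 699, 1947, 132 and 3812. With spike-in scaling 113 probe sets were above and 63 below both parents in the A. lyrata cross, and 133 and 17 in the A. halleri cross. With the class as a block these were 456 and 346, and 95 and 69. With 1 array left out these counts moved by over 1.5 times: the totals against A. thaliana ranged from 272 (without A. thaliana-A. lyrata hybrid replicate 1) to 3583 (without A. thaliana replicate 1) and from 120.0 (without A. thaliana-A. halleri hybrid replicate 1) to 2432 (without A. thaliana replicate 1), those against the other parent from 1021 (without A. thaliana-A. lyrata hybrid replicate 1) to 4942 (without A. thaliana replicate 2) and from 597 (without A. thaliana-A. halleri hybrid replicate 1) to 3975 (without A. thaliana replicate 1), and those above or below both parents from 17 (without A. thaliana-A. lyrata hybrid replicate 1) to 801 (without A. thaliana replicate 1) and from 6 (without A. thaliana-A. halleri hybrid replicate 1) to 370.0 (without A. thaliana replicate 1).

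Positions have 0 at the other parent, 1 at A. thaliana and 0.5 at mid-parent. Probe sets at least 4-fold higher in A. thaliana had a median position of 0.378 ± 0.0675 (SD over 2 hybrid arrays, 1471 probe sets) in the A. thaliana-A. lyrata hybrid. Those at least 4-fold higher in A. lyrata had 0.726 ± 0.00138 (1846 probe sets). In the A. thaliana-A. halleri hybrid the positions were 0.461 ± 0.00628 (1221 probe sets) and 0.684 ± 0.0169 (1569 probe sets). In both hybrids the signal thus lay nearer to the weaker parent in either direction, except that the position of 0.461 became 0.50 and 0.506 without A. halleri replicates 1 and 2. With spike-in scaling the positions were 0.281 and 0.552 in the A. lyrata cross and 0.463 and 0.375 in the A. halleri cross, so that the last of these moved to the side of the stronger parent. They are medians without a test, and the parents' arrays that chose these probe sets also set the scale. That choice can by itself move an additive hybrid toward the weaker parent.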

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

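Of the tests below, the comparison of bright signals between species was written down before its result was seen, and the other tests of explanations were chosen after theirs were. The test of the difference between the hybrids was planned.

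The hybrids differed in how genes departed from mid-parent. By limma's test of the difference, 50 probe sets deviated upward in the A. thaliana-A. lyrata hybrid relative to the other hybrid and 123 in the opposite direction. The largest named differences were 7.20 for BHLH101, 2.71 for CCS and 2.26 for ECS1, and -8.07 for AOP3, -5.92 for CML38 and -4.84 for STZ (log2). BHLH101 was at 334 and 498 on the A. thaliana-A. lyrata hybrid arrays and at 5.79 and 5.89 on the other hybrid's, below the offset. AOP3 was at 51.6 and 13.4 against 9714 and 8241. Of the 6 only AOP3 kept its call with each array left out in turn. No explanation was tested for these genes.

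The bacterial and phage controls were brighter relative to leaf signal outside A. thaliana, after rescaling 3.64-fold brighter in A. lyrata, 2.49-fold in A. halleri, 1.79-fold in the A. thaliana-A. lyrata hybrid and 1.2-fold in the A. thaliana-A. halleri hybrid. A candidate explanation is sequence difference from the A. thaliana probes, which should spare slowly evolving organelle genes, and on the spike-in scale the chloroplast and mitochondrial lists lay above all probe sets by at least 0.910 (medians, log2) in both species. It stays open, since organelle transcripts that are more abundant would give this too, the mitochondrial list did not pass on that scale in A. lyrata (adjusted p = 0.0888), and the median of 4 conserved reference genes was -1.02 against -1.57 for all in A. lyrata but -1.26 against -1.02 in A. halleri. Less labelled leaf RNA on those arrays remains open as the whole cause too: the gap between A. thaliana and the other species in the ratio of 95th to 75th percentile signal was 0 (2.29 to 2.52 in A. thaliana, 2.41 to 2.49 in the others, log2), as a uniform loss would give, but that of 99th to 75th percentile was 3.86 to 4.27 and 4.56 to 4.81. Species differences in total leaf RNA were not tested.

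Chloroplast transcripts that were at least 4-fold higher in A. lyrata lay near the A. thaliana level in its hybrid. Their position was 0.937 (21 probe sets, mean of the medians on 2 arrays, 1 being A. thaliana) against 0.724 for other probe sets. With the scale class as a block it was 0.964 against 0.677. None of the random draws of as many other probe sets lay as high. The draws treat probe sets as independent, which genes of 1 chloroplast genome are not, so they can overstate the evidence. Array scaling as the whole cause is argued against by the position on the spike-in scale, 1.05 (4 probe sets) against 0.541. The values are consistent with plastids inherited from the A. thaliana parent, a hypothesis, since the direction of the cross is not given. In the A. thaliana-A. halleri hybrid the position was 0.729 against 0.683 and 0.866 against 0.358 on the spike-in scale (6 probe sets). With the block it was lower, 0.676 against 0.712. Random draws lay at least as high in 8.56%, 0.230% and 46.6% of cases, so the plastid parent stays open there.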

How the results depend on the processing

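The scale class as a block, the fit within 1 class, the deposited values and spike-in scaling with the block were chosen after the data were seen, and the last 2 cover counts of calls alone. Over all alternatives except left-out arrays, 229 of 329 counts and positions stayed within 1.5 times (counts) or within the SD over the hybrid arrays (positions), and 100 did not. eBayes with robust settings, a 2-fold minimum and the estimated correlation for lists changed none of the counts and positions they cover. Of 155 values of named genes, 126 kept direction and call with spike-in scaling, 24 lost their call and 5 changed sign, and with the scale class as a block these were 133, 18 and 1, and 3, all of GI, whose A. thaliana arrays lie far apart, gained a call. The cause of the changes below was not tested, except where it follows by construction. A stricter threshold calls fewer probe sets, and the deposited values keep the unlike scales of the 2 classes. The class as a block, and leaving out an A. thaliana array, take the difference between the A. thaliana arrays out of the shared spread. The signal over background limits what weak probe sets can show. The A. lyrata cross and the A. halleri cross are the hybrids of these species with A. thaliana.

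With spike-in scaling, the count was 393 for the difference between the hybrids, 4419 for the A. lyrata cross against A. thaliana, 5391 for the A. lyrata cross against A. lyrata and 5644 for the A. halleri cross against A. halleri. It was 150 for probe sets outside both parents in the A. halleri cross and 6895 for calls shared by the species. Median positions were 0.281 (higher in A. thaliana, A. lyrata cross), 0.552 (higher in A. lyrata) and 0.375 (higher in A. halleri). The log2 difference changed sign to -0.51 for FMA in A. lyrata, -0.59 for RCA in A. lyrata, -0.57 for ZIP6 in A. lyrata, -0.54 for GI in A. lyrata and -0.11 for PWD in A. halleri. Lists that passed in neither fit turned direction, with adjusted p = 0.302 (photosynthesis genes, A. lyrata against A. thaliana), 0.503 (photosynthesis genes, A. halleri against A. thaliana), 0.726 (chloroplast genes, A. halleri against A. lyrata) and 0.726 (photosynthesis genes, A. halleri against A. lyrata). With spike-in scaling and the class as a block, the count was 11161 for A. lyrata against A. thaliana, 3554 for the A. lyrata cross against mid-parent, 900 for the A. halleri cross against mid-parent and 2622 for the difference between the hybrids. It was 7201 for the A. lyrata cross against A. thaliana, 6888 for the A. lyrata cross against A. lyrata and 7233 for the A. halleri cross against A. halleri. With quantile normalization, the median position was 0.751 (higher in A. lyrata), 0.472 (higher in A. thaliana, A. halleri cross) and 0.711 (higher in A. halleri). The log2 difference changed sign to -0.28 for RCA in A. lyrata. The lists that turned with spike-in scaling turned here too and passed in neither fit. In the same order, adjusted p was 0.213, 0.279, 0.789 and 0.789. With 75th-percentile scaling, the median position was 0.699 (higher in A. lyrata) and 0.474 (higher in A. thaliana, A. halleri cross). On the deposited values without rescaling, the count was 13125 for A. lyrata against A. thaliana, 19104 for A. halleri against A. lyrata, 3583 for the A. lyrata cross against mid-parent and 23 for the A. halleri cross against mid-parent. It was 4023 for the difference between the hybrids, 10889 for the A. lyrata cross against A. thaliana, 1000 for the A. lyrata cross against A. lyrata and 519 for the A. halleri cross against A. halleri. The offset and the low-signal cutoff were set anew for each scaling, so that 16522 probe sets were tested with spike-in scaling and 20028 on the deposited values.

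The block and the fit within 1 class make the same contrasts with 1 A. thaliana array, and so are not independent. With the scale class as a block, the count was 2728 for the A. lyrata cross against mid-parent, 544 for the A. halleri cross against mid-parent, 684 for the difference between the hybrids and 3566 for the A. lyrata cross against A. thaliana. It was 3917 for the A. halleri cross against A. halleri, 802 for probe sets outside both parents in the A. lyrata cross, 164 for probe sets outside both parents in the A. halleri cross and 165 for calls shared by the hybrids. Hybrid positions had medians of 0.30 (higher in A. thaliana, A. lyrata cross), 0.680 (higher in A. lyrata), 0.487 (higher in A. thaliana, A. halleri cross) and 0.712 (higher in A. halleri). The log2 difference changed sign to -0.10 for GI in A. lyrata. Lists that passed in neither fit turned direction, with adjusted p = 0.911 (photosynthesis genes, A. halleri against A. thaliana), 0.594 (chloroplast genes, A. halleri against A. lyrata) and 0.906 (mitochondrial genes, A. halleri against A. lyrata). Within 1 scale class, the count was 1921 for the A. lyrata cross against mid-parent, 314 for the A. halleri cross against mid-parent, 4436 for the A. halleri cross against A. halleri and 594 for probe sets outside both parents in the A. lyrata cross. It was 182 for probe sets outside both parents in the A. halleri cross. Hybrid positions had medians of 0.309, 0.675, 0.486 and 0.708, in the order above. The log2 difference changed sign to -0.10 for GI in A. lyrata. Lists that passed in neither fit turned direction, with adjusted p = 0.886 (photosynthesis genes, A. halleri against A. thaliana).

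With only the arrays compared in the fit, the count was 4072 for A. lyrata against A. thaliana, 3918 for A. halleri against A. thaliana, 143 for the A. lyrata cross against mid-parent and 10 for the A. halleri cross against mid-parent. It was 167 for the A. lyrata cross against A. thaliana, 56 for the A. halleri cross against A. thaliana, 4572 for the A. halleri cross against A. halleri and 22 for probe sets outside both parents in the A. lyrata cross. It was 9 for probe sets outside both parents in the A. halleri cross, 2 for calls shared by the hybrids and 2044 for calls shared by the species. Median positions were 0.734 (higher in A. lyrata) and 0.468 (higher in A. thaliana, A. halleri cross). Lists that passed in neither fit turned direction, with adjusted p = 0.931 (photosynthesis genes, A. halleri against A. lyrata). At an adjusted p below 0.01, the count was 3924 for A. lyrata against A. thaliana, 3326 for A. halleri against A. thaliana, 951 for A. halleri against A. lyrata and 105 for the A. lyrata cross against mid-parent. It was 8 for the A. halleri cross against mid-parent, 49 for the difference between the hybrids, 457 for the A. lyrata cross against A. thaliana and 1053 for the A. lyrata cross against A. lyrata. It was 184 for the A. halleri cross against A. thaliana, 789 for the A. halleri cross against A. halleri, 23 for probe sets outside both parents in the A. lyrata cross and 9 for probe sets outside both parents in the A. halleri cross. It was 2 for calls shared by the hybrids and 1951 for calls shared by the species. Median positions were 0.723 (higher in A. lyrata) and 0.486 (higher in A. thaliana, A. halleri cross). With eBayes without trend, the count was 536 for the A. lyrata cross against mid-parent, 53 for the A. halleri cross against mid-parent, 160 for probe sets outside both parents in the A. lyrata cross and 59 for probe sets outside both parents in the A. halleri cross. It was 15 for calls shared by the hybrids. With a mid-parent on the log scale, the count was 359 for the A. halleri cross against mid-parent and 152 for calls shared by the hybrids. Calls above mid-parent outnumbered those below on the log scale, unlike on the arithmetic scale, with 544 against 398 in the A. lyrata cross, 266 against 93 in the A. halleri cross and 125 against 27 in both. With parents at least 2-fold apart, the median position was 0.712 (higher in A. lyrata) and 0.488 (higher in A. thaliana, A. halleri cross).

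Without an offset, the count was 118 for the A. halleri cross against mid-parent. Median positions were 0.711 (higher in A. lyrata) and 0.476 (higher in A. thaliana, A. halleri cross). With the offset at the 30th percentile, the count was 317 for the A. halleri cross against mid-parent and 110 for calls shared by the hybrids. Median positions were 0.765 (higher in A. lyrata), 0.439 (higher in A. thaliana, A. halleri cross) and 0.712 (higher in A. halleri). Without a low-signal filter, the median position was 0.740 (higher in A. lyrata). With a filter at the 60th percentile, the median position was 0.744 (higher in A. lyrata). With only probe sets of plain identifiers, the median position was 0.723 (higher in A. lyrata).

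The replicate numbers do not pair the arrays: deviations of same-numbered arrays correlated across probe sets with 0.264 between A. thaliana and the A. thaliana-A. lyrata hybrid and with -0.126 to 0.0178 between other groups. The replicate block lowered the calls of the A. halleri cross against mid-parent to 117, and changed no other count by over 1.5 times.

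With each array left out in turn, a group left with 1 array was assumed to vary like the others. Values ranged from 5247 (without A. lyrata replicate 1) to 7098 (without A. thaliana replicate 1) for A. lyrata against A. thaliana and 3670.0 (without A. halleri replicate 2) to 6655 (without A. thaliana replicate 1) for A. halleri against A. thaliana. The range was 1110.0 (without A. halleri replicate 2) to 3855 (without A. thaliana replicate 1) for A. halleri against A. lyrata and 36 (without A. thaliana-A. lyrata hybrid replicate 1) to 2764 (without A. thaliana replicate 1) for the A. lyrata cross against mid-parent. Values ranged from 6 (without A. thaliana-A. halleri hybrid replicate 2) to 1254 (without A. thaliana replicate 1) for the A. halleri cross against mid-parent and 16 (without A. thaliana-A. halleri hybrid replicate 2) to 457 (without A. thaliana replicate 1) for the difference between the hybrids. The range was 272 (without A. thaliana-A. lyrata hybrid replicate 1) to 3583 (without A. thaliana replicate 1) for the A. lyrata cross against A. thaliana and 1021 (without A. thaliana-A. lyrata hybrid replicate 1) to 4942 (without A. thaliana replicate 2) for the A. lyrata cross against A. lyrata. Values ranged from 120.0 (without A. thaliana-A. halleri hybrid replicate 1) to 2432 (without A. thaliana replicate 1) for the A. halleri cross against A. thaliana and 597 (without A. thaliana-A. halleri hybrid replicate 1) to 3975 (without A. thaliana replicate 1) for the A. halleri cross against A. halleri. The range was 17 (without A. thaliana-A. lyrata hybrid replicate 1) to 801 (without A. thaliana replicate 1) for probe sets outside both parents in the A. lyrata cross and 6 (without A. thaliana-A. halleri hybrid replicate 1) to 370.0 (without A. thaliana replicate 1) for probe sets outside both parents in the A. halleri cross. Values ranged from 0.252 (without A. thaliana replicate 1) to 0.424 (without A. lyrata replicate 1) for the position of probe sets higher in A. thaliana, A. lyrata cross and 0.635 (without A. thaliana replicate 1) to 0.760 (without A. lyrata replicate 1) for the position of probe sets higher in A. lyrata. The range was 0.348 (without A. thaliana replicate 1) to 0.506 (without A. halleri replicate 2) for the position of probe sets higher in A. thaliana, A. halleri cross and 0.609 (without A. thaliana replicate 1) to 0.721 (without A. halleri replicate 1) for the position of probe sets higher in A. halleri. Values ranged from 1 (without A. thaliana-A. lyrata hybrid replicate 1) to 710.0 (without A. thaliana replicate 1) for calls shared by the hybrids and 2576 (without A. halleri replicate 2) to 4431 (without A. thaliana replicate 1) for calls shared by the species. The number of list results past the threshold, 9, ranged from 8 (without A. thaliana replicate 2) to 9. GI in A. lyrata against A. thaliana ranged from -0.10 (without A. thaliana replicate 1) to 2.67 (without A. thaliana replicate 2) on the log2 scale. The adjusted p of nuclear photosynthesis genes in A. lyrata against A. thaliana ranged from 0.132 (without A. thaliana replicate 1) to 0.887 (without A. thaliana replicate 2). In A. halleri against A. thaliana it ranged from 0.115 to 0.900, with the same arrays left out. The adjusted p of chloroplast genes in A. halleri against A. lyrata ranged from 0.638 (without A. halleri replicate 1) to 0.994 (without A. halleri replicate 2). That of nuclear photosynthesis genes there ranged from 0.671 to 0.994, with the same arrays left out.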

Other observations

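All tests of explanations below, and the gene families, were chosen after the data were seen.

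Gene families set by shared symbols were tested, and those that passed are given here. Photosynthesis complexes encoded in the chloroplast were higher in A. lyrata (22 of 33 higher, cameraPR adjusted p = 1.65e-07) and in A. halleri (20 higher, 2.46e-08), and lower than mid-parent in the A. thaliana-A. lyrata hybrid (10 lower, 0.000277; 0.229 with spike-in scaling). On the spike-in scale 10 of them were lower and 3 higher in A. lyrata. Chloroplast genes of transcription and translation were higher in A. lyrata (15 of 20, 0.000231) and A. halleri (13, 0.000905), but not with an estimated correlation (0.0788 and 0.175). GH9 glycoside hydrolases, cell-wall enzymes, were higher in A. lyrata (7 of 9, 0.00764; 0.107 with an estimated correlation, 0.117 with the scale class as a block). In the A. thaliana-A. lyrata hybrid against mid-parent, calmodulin-like genes stood below other genes by cameraPR (3 of 7 called, 0.000277, with 7.86e-05 under spike-in scaling and 0.00535 with the block). Autophagy genes stood below other genes there too (0.0214, but 0.487 with an estimated correlation). In the A. thaliana-A. halleri hybrid against mid-parent, NADH dehydrogenase-like complex genes stood above other genes by cameraPR (1.09e-05, and 0.0347 with an estimated correlation).

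The A. thaliana replicates differed more than those of any other group, with 1012 probe sets (6.08%) at least 4-fold apart, against 4.66% in A. lyrata and 1.34% in the A. thaliana-A. halleri hybrid. Signals of replicates 1 and 2 were 12.9 and 13384 for the anthocyanin gene DFR, 21.0 and 5444 for UF3GT, 33.7 and 547 for AT5MAT and 352 and 14067 for the photosystem I gene psaA, and 982 and 35.0 for the stomatal peptide gene STOMAGEN and 919 and 21.6 for the expansin gene EXPA8. The difference between the scale classes as the whole cause is argued against by all 1012: in the direction of replicate 2, the unscaled hybrid differed from the scaled hybrid by a median of -0.217 (quartiles -0.860 and 0.404) and A. lyrata from A. halleri by 0.101 (-0.708 and 1.02), where about 2.46 would be needed (log2). These groups also differ in species, so a part from the class stays open. A wrong label for an array of another group is argued against by the highest correlation with such an array, 0.830, against 0.878 with replicate 1 (across probe sets, which are not independent replicates). The labels give the plants no difference, so no biological explanation was tested.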
